A study of Rattus norvegicus with 12 samples.

How the data were processed

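RNA from the microdissected CA1 region of 12 rats was hybridised to 12 Affymetrix RAE230A arrays, 1 array per animal, 6 after a control task and 6 after spatial learning. Groups and replicate numbers were taken from the sample titles, which call the arrays biological replicates. CA3 and dentate gyrus were also dissected, per the labels' protocols, and are not analysed here. Scan dates and hybridisation batches are not given in the sources used here, so no batch could be tested.

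The deposited values are 1 table of log2 probe set summaries. The submitters' processing notes name GCRMA, which corrects each probe for background using its sequence, normalizes between arrays and summarises the probes of a probe set, and no version or setting is given in the sources used here. That the authors' values are on a log2 scale was settled from their range, 0.134 to 14.8, since natural or base-10 logs reaching 14.8 would exceed what a scanner can record. GCRMA makes the arrays' distributions nearly equal, so that a change in the total amount of RNA cannot be seen, and it compresses differences of dim probe sets near background.

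The table holds 15923 probe sets, of which 57 are manufacturer's controls. Probe sets were named through the platform annotation supplied with the table, which can be old: 12783 have 1 gene symbol, 312 have several and 2771 have none here. For 12748 of the single-symbol probe sets the Entrez identifier was found in a reference table of rat genes on the GRCr8 assembly, and 0 symbols needed updating. No gene was named from a probe set with several symbols. No coordinates are given, since no genome was used.

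Probe sets other than controls with a mean of at least 4 (log2) over all 12 arrays were tested, 9610 of 15866, covering 6867 named genes. The remaining 6256 were left out as too dim. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, 2-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. SEs are limma's moderated ones. The 34 gene lists, with 1107 members of which 919 have a probe set, were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives except those said to be added. Each gene entered a list through its probe set with the highest mean over all arrays. The 32 lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, with the correlation estimated, and with fry, which tests whether a set's genes move one way on balance and does not compare them with other genes. Metabotropic glutamate receptors, with 3 tested genes, and blood markers, with 4, were too small. The synaptic vesicle, CA1 and dentate calls passed only with the preset correlation: with the correlation estimated and with fry, 0 lists passed.

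Per-array list means and the control measures were compared by 2-sided exact permutation tests over the 924 ways to choose 6 of 12 arrays, whose smallest p is 0.00216. The 5 control measures were the 3' minus 5' signal of the beta-actin, Gapdh and hexokinase controls and the means of the hybridisation and labelling spikes. The beta-actin gap was 1.83 in the control task group and 1.93 in the spatial learning group (exact permutation p = 0.0779), the Gapdh gap 0.37 in both (exact permutation p = 0.998), the hybridisation spikes 9.75 and 9.88 (exact permutation p = 0.106) and the labelling spikes 3.04 and 3.10 (exact permutation p = 0.0455, adjusted over the 5 measures 0.114). The labelling spikes lay below the level of 4 under which probe sets were left out as too dim, so they may tell little about labelling. Correlations across arrays used 100000 permutations. The RNA quality covariate used below was each array's mean of the beta-actin and Gapdh gaps, and left out hexokinase.

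Named genes followed a fixed rule. It took the first 10 single-symbol genes by unadjusted p in each direction, since no probe set passed, up to 4 members of each list by smallest p, and a set of genes chosen beforehand for activity, glutamate receptors and tissue purity. How many list members to name, 4 for the called and the activity lists and 2 for the others, was set after values were seen. Of the genes chosen beforehand, Egr3 was below the filter and Nptx2 had no probe set with a single symbol.

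The whole procedure was tested on simulated data drawn with the real means and spreads for this comparison, with 9592 probe sets tested. Of 100 probe sets changed by 0.5 (log2), 89% were recovered, and of 100 changed by 1, 96%, with 11 unchanged probe sets called. A shift of -0.1 put on the synaptic vesicle list gave a camera adjusted p of 3.88e-10 and 0 other lists were called. The simulated noise was independent between probe sets, whereas the real synaptic vesicle list had an estimated correlation of 0.105. The simulation therefore does not show how the list test behaves with correlated genes.

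Alternatives tried were no filter and a filter at 6, quantile normalization and a common median per array, eBayes without the trend and with robust settings, array weights, the replicate number as a block, covariates for CA3 and dentate markers, choroid plexus markers and RNA quality, leaving out each array, an exact rank-sum test, 1 probe set per gene, an adjusted p of 0.10, and the mean or the most variable probe set of a gene in the lists. Added after seeing the data were fits without control replicates 3 and 6, fits without these and spatial learning replicate 6, the hexokinase gap as a covariate, chosen because it was seen to differ, the synaptic vesicle list without Cplx2 and Slc17a6, and the lists without the 3 arrays with the correlation estimated. The robust setting does not enter the list tests, so its list results repeat the main fit, although it is counted among the other fits of the lists. The counts of calls were also compared with those of 100 splits of the 12 arrays into 6 and 6, drawn from 462, the real split included.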

Results

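RNA levels were measured in the CA1 region of the hippocampus, the output field of the hippocampal circuit, of 12 young male Long-Evans rats. The rats were 3 to 4 months old. Each animal gave 1 Affymetrix RAE230A array, a 1-colour array of 25-base probes grouped into probe sets, and the arrays fell into 2 groups of 6. All rats had been trained in a water maze 2 to 3 weeks earlier and then swam 8 trials, 8 minutes apart, in a new maze. The spatial learning group swam with orienting cues and a visible platform that stayed in one place. The control task group swam to a visible platform that moved from trial to trial, without informative cues. A probe trial of 90 seconds without the platform followed 1 hour after the last trial, and tissue was taken straight after it. Over the probe sets, the correlation between any 2 arrays lay between 0.996 and 0.998, and the number of arrays, 6 per group, limits the precision. The comparison asks which transcripts in CA1 differ after a session in which a place could be learned from a session with as many trials and no stable place. All differences below are spatial learning minus control task on the log2 scale.

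The 2 groups had closely similar CA1 transcript levels, and no single transcript passed the test. On the higher side the first ranked was Dgkz, a diacylglycerol kinase, at 11.80 ± 0.10 in the control task group and 12.18 ± 0.12 in the spatial learning group (log2, mean ± SD, n = 6 each). Its difference was 0.38 with a limma adjusted p of 0.128. On the lower side Cit, which encodes citron kinase, ranked first, at 8.19 ± 0.12 and 7.73 ± 0.14, a difference of -0.46 with the same limma adjusted p of 0.128. In both genes the values of the 6 spatial learning arrays lay entirely on one side of the 6 control values. Both were picked by their p from 9610 probe sets, so this separation largely follows from the choice and adds no support. Of 9610 probe sets tested, 0 passed at an adjusted p of 0.05 and 0 at 0.10 with limma, while 1048 had an unadjusted p under 0.05, 611 of them higher and 437 lower, where 480.5 would come by chance with no effect. The exact rank-sum test also called 0, with a smallest adjusted p of 0.341. In 92.2% of the tested probe sets the difference was under 0.2 in size, and the median SE of a difference was 0.07.

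The other genes ranked first on the higher side, none past the threshold, were Adprs at 0.28, Bok (a BCL2 family protein) at 0.37, Susd6 at 0.33, Map4 (a microtubule-associated protein) at 0.20, Fndc5 (the precursor of irisin) at 0.17, Nipsnap3b at 0.28, Tsc22d1 at 0.13, Ralgapb at 0.25 and Mast3 at 0.19. Second probe sets of Bok and Map4 gave 0.40 and 0.24, whereas those of Ralgapb and Mast3 gave -0.02 and -0.07. On the lower side came Gnas (the stimulatory G protein subunit) at -0.22, Aqp4 (the astrocyte water channel) at -0.42, Map1b at -0.60, Tef (a clock-controlled transcription factor) at -0.68, Sptbn1 at -0.22, Rgs4 (a regulator of G protein signalling) at -0.67, Arpp21 at -0.35 and Bsn (Bassoon, of the presynaptic active zone) at -0.59. Slc1a2, the main astrocyte glutamate transporter, stood at 6.81 ± 0.41 in the control task group and 5.81 ± 0.36 in the spatial learning group (n = 6 each) and had the widest gap of these. Rgs4 had a second probe set at -0.47. The 2 other probe sets of Aqp4 gave -0.18 and -0.09, those of Sptbn1 -0.32 and -0.0084, and those of Arpp21 -0.17 and 0.19. The second probe sets of Gnas, Map1b, Bsn and Slc1a2, which were brighter, gave -0.00, -0.10, 0.02 and -0.19.

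Genes induced by neuronal activity did not pass the test as sets. Fos, the immediate early transcription factor, stood at 7.25 ± 0.34 in the control task group and 6.46 ± 0.47 in the spatial learning group, a difference of -0.79 (SE 0.21, n = 6 each), with 5 of the 6 spatial learning arrays below the lowest control. The exact permutation p was 0.00649, unadjusted, and the limma p did not pass after adjustment over all probe sets (limma adjusted p = 0.348). Egr1 at 0.04, Egr2 at 0.04, Junb at 0.02, Arc (a synaptic cytoskeletal protein) at 0.01, Dusp1 at -0.02 and Bdnf at 0.05 lay near 0, while Nr4a1 stood at -0.11 and Sgk1 at -0.26, with SEs from 0.04 to 0.17 over these 8. Of the 22 transcription factors in the activity list, 9 were higher and 13 lower, and 0 passed adjusted over the list alone or over all probe sets. Besides Fos, Jun at -0.29, Klf4 at -0.32 and Nr4a3 at -0.11 had unadjusted p under 0.05, and the list median was -0.01 (camera adjusted p = 0.152). Of the 28 other activity genes 13 were higher and 15 lower, with a median of -0.02 (camera adjusted p = 0.262) and 0 past the threshold either way. Those with the smallest p were Rgs4 at -0.47 on its brightest probe set, Rasd1 at 0.30, Homer1 at 0.32 and Rasl11b at 0.44. The remaining 4 Homer1 probe sets ranged from -0.12 to 0.10. Egr3 lay below the level filter, with a mean of 3.90, and Nptx2 is not analysed here.

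**Figure D1:**
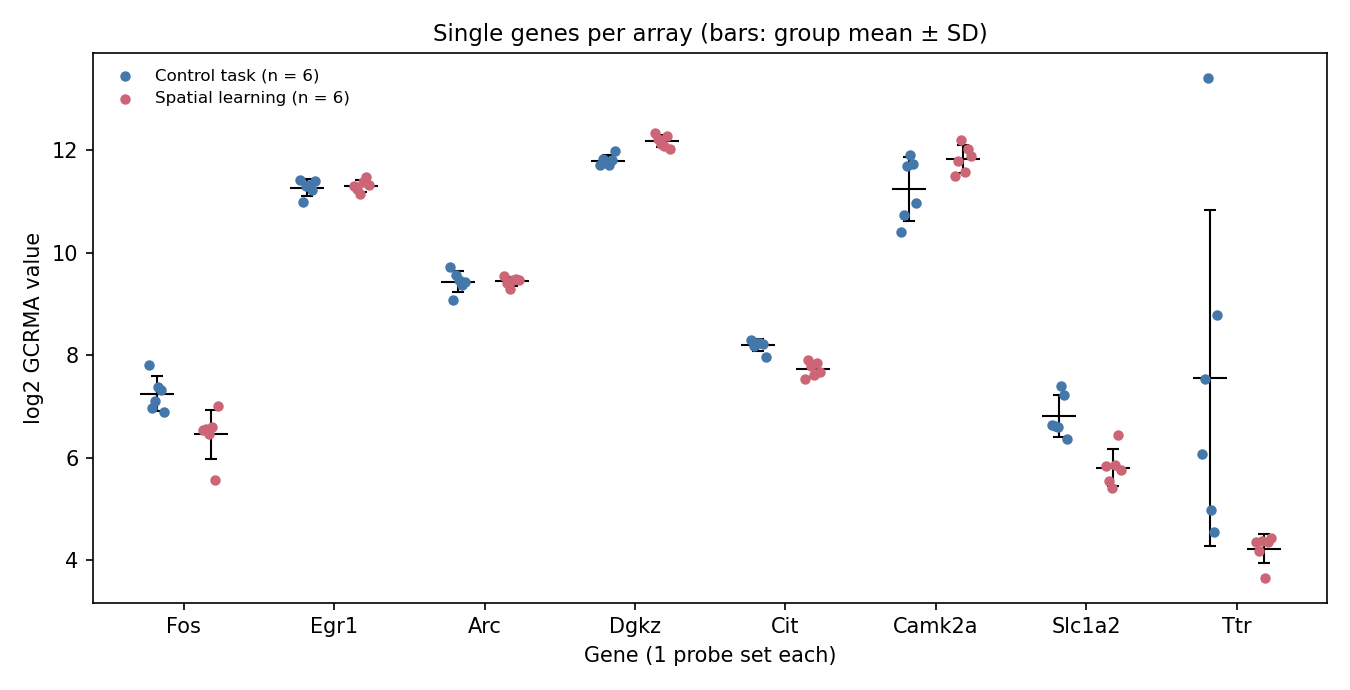
Log2 GCRMA values of 8 genes on the vertical axis, 1 probe set each, with 1 point per array for the control task group (blue, n = 6) and the spatial learning group (red, n = 6) and black bars for the mean ± SD. Fos, Cit and Slc1a2 had lower spatial learning means, Egr1 and Arc had nearly equal means, and Ttr spread from 4.55 to 13.41 within the control task group.

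The synaptic vesicle list was called lower as a set by camera with the preset correlation only. Of its 29 tested genes, which encode proteins of the presynaptic vesicle cycle, 22 were lower and 7 higher after spatial learning, with a median of -0.11 (camera adjusted p = 8.46e-06 with the preset correlation). The adjusted p was 0.355 with an estimated correlation, and 0.301 with fry. Cplx2, a complexin that regulates vesicle fusion, differed by -0.77 (SE 0.22). Slc17a6 and Slc17a7, the vesicular glutamate transporters, differed by -0.73 and -0.18, and Syt11 by -0.13. No member passed by itself, 0 adjusted over the list alone and 0 over all probe sets, and 6 of the lower members had an unadjusted p under 0.05. The list mean per array was 9.37 ± 0.05 in the control task group and 9.25 ± 0.05 in the spatial learning group (log2, mean ± SD, n = 6 each), all 6 spatial learning arrays lying below all 6 controls. The exact permutation p was 0.00216, the smallest that 6 against 6 can give, and 0.0693 after adjustment over the 32 lists. Without Cplx2 and Slc17a6, an alternative chosen after seeing the data, the mean difference was -0.07 over 27 genes. Of the 6 spatial learning arrays, 5 then lay below all controls (exact permutation p = 0.00866, unadjusted). Slc17a6 is also in the list of neighbouring brain region markers. The signal gap between the 3' and 5' ends of the hexokinase control transcript, a measure of RNA integrity, moved with the groups too, at 1.48 ± 0.08 in the control task group and 1.65 ± 0.11 in the spatial learning group (log2, exact permutation p = 0.00433, adjusted over 5 control measures 0.0216).

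**Figure D2:**
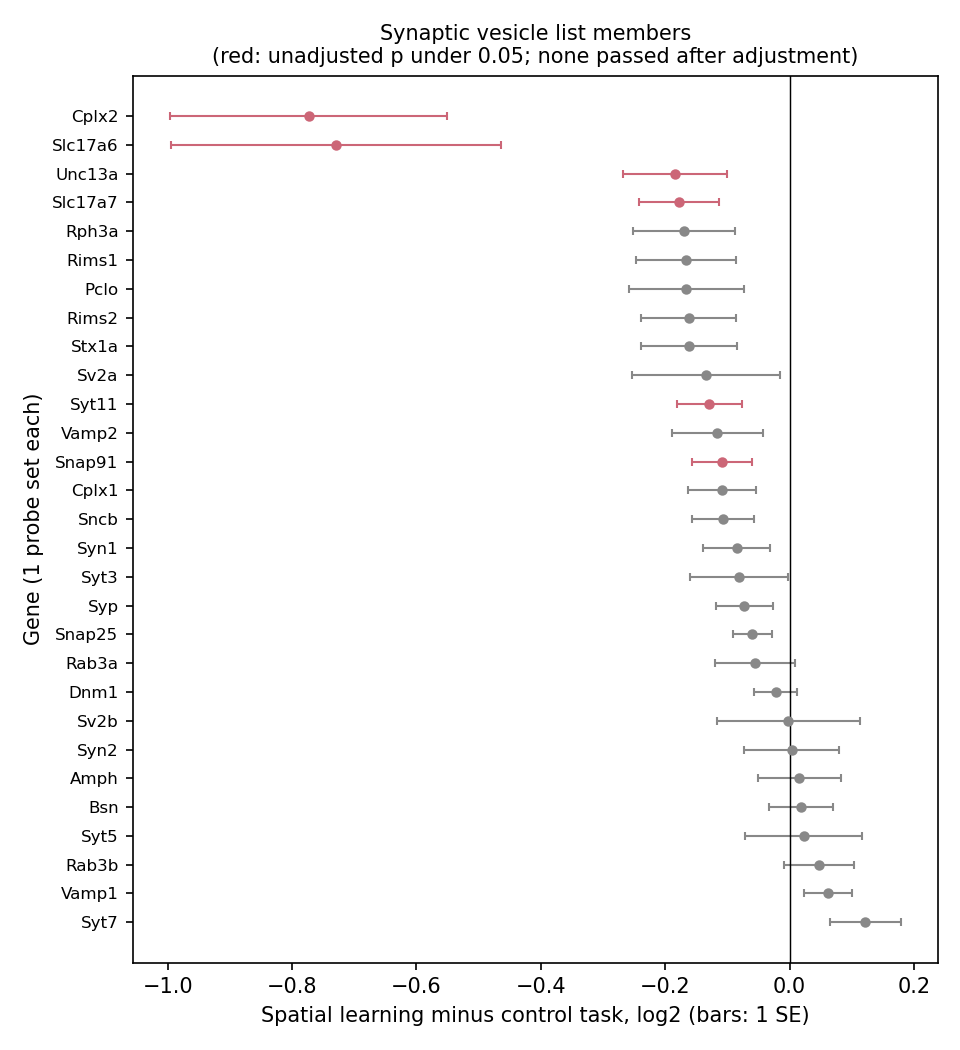
Spatial learning minus control task difference in log2 on the horizontal axis for each of the 29 synaptic vesicle genes (vertical axis), with bars of 1 SE, red where the unadjusted p was under 0.05. Cplx2 at -0.77 and Slc17a6 at -0.73 lie farthest from 0, and the other 20 lower members lie between -0.18 and 0.

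Markers of the hippocampal fields moved in different directions. CA1 markers were called higher as a set with the preset correlation only (camera adjusted p = 0.0110). The adjusted p was 0.416 with an estimated correlation and 0.301 with fry. Of these markers 8 of 9 were higher, with a median of 0.14. Itpka, an inositol trisphosphate kinase of dendritic spines, at 0.27, Fibcd1 at 0.36 and Wfs1 (wolframin) at 0.29 passed adjusted over the list alone, and 0 did over all probe sets. The fourth by p was Gpr161 at 0.14. Dentate gyrus markers were called lower as a set, again with the preset correlation only (camera adjusted p = 0.0466). Their adjusted p was 0.416 with an estimated correlation and 0.385 with fry. Of these, 7 of 9 were lower, with a median of -0.19. The dentate list was called lower in 16 of 31 other fits, among them robust eBayes, which does not enter the list tests. Its members with the smallest p were Jun at -0.29, Trpc6 at -0.19, Stxbp6 at -0.32 and Sema5a at -0.23, with 0 passing adjusted over the list alone. The per-array means gave exact permutation p of 0.0325 for CA1 and 0.0606 for dentate markers, both 0.346 after adjustment. CA3 markers did not pass (median 0.07, camera adjusted p = 0.262), with Bok, also named above, passing adjusted over the list alone and Nnat (neuronatin) at -0.34. With the per-array mean of the CA3 and dentate lists as a covariate, the CA1 median was 0.060 (adjusted p = 0.0825) and the dentate median -0.060 (adjusted p = 0.207), and neither call remained. That covariate is built partly from the dentate list's own members, so the loss of the dentate call was largely fixed by construction.

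**Figure D3:**
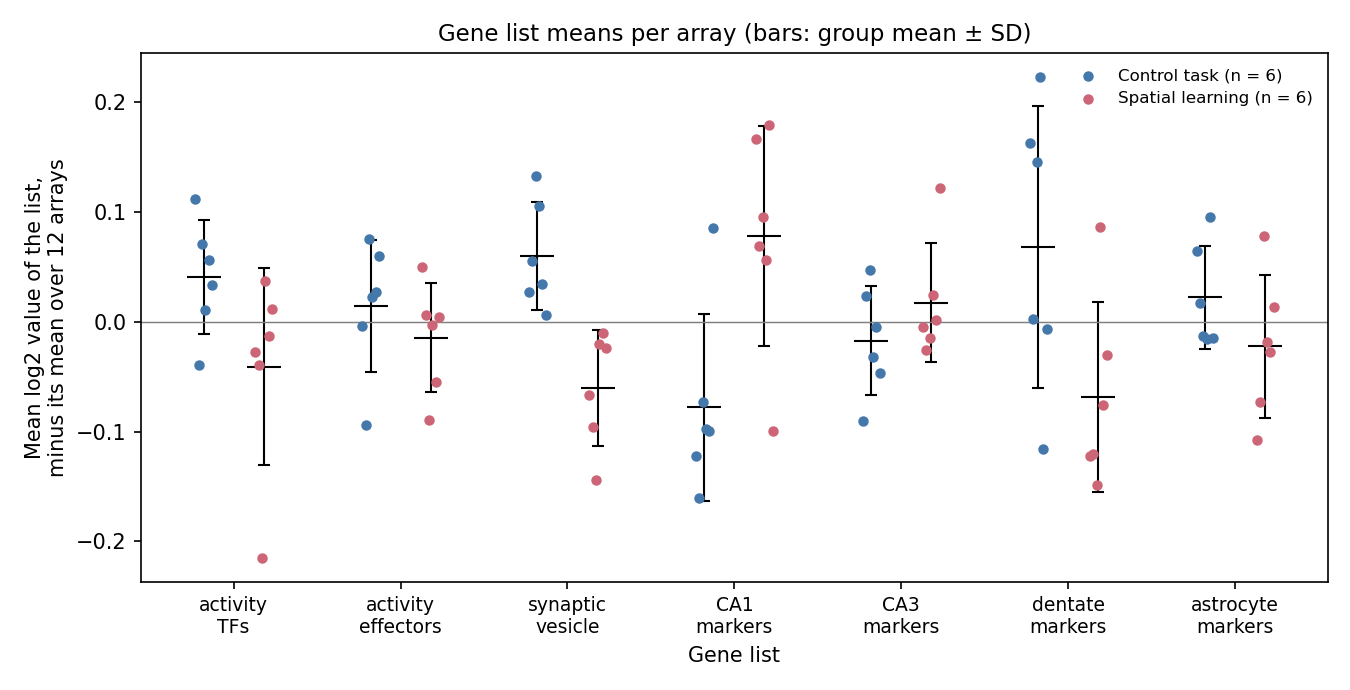
Mean log2 value of 7 gene lists per array, minus the list's mean over the 12 arrays (vertical axis), with 1 point per array for the control task group (blue, n = 6) and the spatial learning group (red, n = 6) and black bars for the mean ± SD. The groups do not overlap in the synaptic vesicle list and do in the other 6.

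Receptors, scaffolds and plasticity enzymes did not pass the test as sets. Among 14 ionotropic glutamate receptor genes 8 were higher (median 0.01, camera adjusted p = 0.450). Gria1 differed by 0.02, Gria2 by -0.04, Grin1 by 0.08, Grin2a by -0.34 (SE 0.35) and Grin2b by -0.03, while Cacng3, an AMPA receptor auxiliary subunit, at 0.37 and Grik5 at 0.18 had the smallest p. GABA receptor subunits had a median of 0.01, a mean of -0.05 and a downward camera test (adjusted p = 0.397), with Gabrg1 at -0.34 and Gabbr2 at -0.21. Postsynaptic scaffold genes had a median of 0.06, a mean of -0.01 and an upward camera test (adjusted p = 0.710), with Homer1 and Grip1 (0.21) ranked first. Of 46 plasticity kinases and phosphatases 26 were higher (median 0.02, camera adjusted p = 0.747). Among these Itpka came first and the transcription factor Creb1 next at -0.32, while Camk2a, the calcium/calmodulin-dependent kinase of the postsynaptic density, stood at 0.59 (SE 0.24, limma adjusted p = 0.434), its other probe sets ranging from -0.17 to 0.13. Camera adjusted p was 0.229 for MAP kinase and PI3 kinase genes (Mapk8 at -0.16, Sos1 at 0.16), 0.262 for neurotrophins and growth factors (Igfbp5 at -0.28, Fgfr1 at 0.15), 0.349 for potassium channels (Kcnj10 at -0.25, Kcnip2 at 0.12) and 0.686 for sodium, calcium and HCN channels (Hcn2 at -0.40, Cacnb2 at 0.16). Cell adhesion and guidance genes had a median of 0.00, a mean of -0.03 and a downward test (camera adjusted p = 0.229), with Cntn1 at -0.26 and Unc5a at -0.27. Cytoskeleton and spine genes were lower in 32 of 45 cases (median -0.03, camera adjusted p = 0.0570), and the list was called lower in 5 of 31 other fits, but the adjusted p was 0.416 with an estimated correlation and 0.578 with fry. Map4, at 0.20, passed adjusted over that list alone, and Arpc2 stood at 0.14.

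Markers of glia, interneurons and vessels did not pass the test either. Astrocyte markers were lower in 15 of 22 genes (median -0.03, camera adjusted p = 0.0567), with Ntsr2 at -0.13 and Agt at -0.17 leading. They were called lower in 14 of 31 other fits, but the adjusted p was 0.548 with an estimated correlation and 0.582 with fry. Oligodendrocyte markers were also lower in 15 of 20 (median -0.04, camera adjusted p = 0.0706), although Cnp stood at 0.19 and Lpar1 at -0.17. They were called lower in 9 of 31 other fits, and the adjusted p was 0.674 with an estimated correlation and 0.582 with fry. Camera adjusted p was 0.229 for microglia (P2ry12 at -0.43, Lyz2 at 0.23), 0.456 for interneurons (Cck at 0.19, Vip at 0.24), 0.456 for vessels (Acta2 at -0.19, Slc2a1 at -0.10; median 0.01, mean -0.02 and a downward test) and 0.224 for neighbouring brain regions (Slc17a6 and Ppp1r1b, the latter at -0.13).

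Ttr, the thyroid hormone carrier transthyretin made by the choroid plexus, had the largest difference of the named genes, at 7.56 ± 3.27 in the control task group and 4.23 ± 0.29 in the spatial learning group (log2, mean ± SD, n = 6 each). All 6 spatial learning arrays lay below all 6 controls (exact permutation p = 0.00216), and the limma adjusted p was 0.423. Control replicate 3 reached 13.41 and control replicate 6 reached 8.79. The choroid plexus list as a whole, of 8 genes, had a median of -0.26 (camera adjusted p = 0.226), with Kcne2 at 0.18, and the 11 meningeal and fibroblast genes a median of -0.04 (camera adjusted p = 0.295), with Gjb2 at -0.31 and Aldh1a2 at -0.04. The hexokinase gap as a covariate was an alternative chosen after seeing the data. With it these medians were -0.43 (camera adjusted p = 0.0135) and -0.33 (camera adjusted p = 0.000168), both with the preset correlation. The lists' estimated correlations were 0.19 and 0.54 without it (camera adjusted p = 0.622 and 0.740), and none was estimated with it. Control replicate 6 and spatial learning replicate 6, highest in the meninges list, also had the largest hexokinase gaps of their groups (1.55 and 1.82). Control replicate 3 also stood highest in the choroid plexus transcripts Enpp2, at 10.94 against at most 9.58 elsewhere, and F5, at 5.34 against at most 3.69. Control replicate 6 and spatial learning replicate 6 shared high Ptgds, at 12.66 and 12.52 against at most 10.94 elsewhere, and high Col1a1, at 6.67 and 6.84 against at most 3.71. Without these 3 arrays, an alternative chosen after seeing the data, 2 probe sets passed higher (Dgkz and Ralgapb) and 3 lower (Bsn, Atp1b2 and a probe set with no gene name here). The oligodendrocyte list then had a median of -0.16 (camera adjusted p = 1.20e-06 with the preset correlation, but 0.363 with an estimated correlation). Without control replicate 6 alone, 1 passed higher (Dgkz) and 2 lower (Cit and the same unnamed probe set). Atp1b2 and the unnamed probe set were singled out after their values were seen.

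Metabolic and stress lists did not pass the test. Oxidative phosphorylation genes were higher in 39 of 60 cases (median 0.04, camera adjusted p = 0.224), with Sdhb at -0.18 and Cox6a1 at 0.09, and ribosomal proteins in 26 of 34 (median 0.02, camera adjusted p = 0.250), with Rps15 at 0.16 and Rps3 at 0.08. Camera adjusted p was 0.456 for proteasome and ubiquitin genes (Psma3 at -0.14, Psmd13 at 0.13), 0.881 for translation factors (Eif3b at 0.13, Eif4ebp2 at -0.14) and 0.865 for heat shock and unfolded protein response genes (Dnajb1 at 0.13, Herpud1 at 0.14). In 3 further lists 1 member passed adjusted over its list alone and 0 over all probe sets. These members were Sqle, which encodes squalene epoxidase, at -0.34 among 15 cholesterol synthesis genes (median -0.03, camera adjusted p = 0.0567, called lower in 11 of 31 other fits but not with an estimated correlation, adjusted p = 0.478, or fry, adjusted p = 0.578, with Idi1 at -0.26), Tef among 13 cold and clock genes (median -0.03, camera adjusted p = 0.0567, with Per1 at -0.19), and Sesn1, at 0.28, among 16 glucocorticoid-responsive genes (median -0.05, camera adjusted p = 0.229, with Ddit4 at -0.21). The mean of the cold and clock list differed by -0.10 (exact permutation p = 0.0238, 0.346 after adjustment), with 4 of the 6 spatial learning arrays below the lowest control. That list was called lower without the filter (adjusted p = 0.0265), with a filter at 6 (0.0438), and with the mean (0.0251) or the most variable probe set (0.0148) of each gene, but not with an estimated correlation (0.355) or fry (0.355).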

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

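The tests of Ttr and of choroid plexus and meningeal tissue, the fits without the arrays concerned and the hexokinase covariate were chosen only after the results were seen.

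In 276 groups of 6 values, from the named genes, the list means and the control measures, 22 arrays lay so far from the rest of their group that the gap to the nearest other array took most of the group's range, where chance alone would give about 13.8. Control replicate 6 accounted for 7 of them and spatial learning replicate 6 for 5. Control replicate 6 was low in Cit (7.97 against at least 8.18 in the other controls), Unc5a (7.71 against at least 8.06) and, minus the mean over all arrays, in the cytoskeleton list (-0.023) and the heat shock list (-0.33), and high in Gria1 (11.55), the CA1 marker list (0.085) and the meninges list (1.05). Spatial learning replicate 6 was low in Gpr161 (10.28) and high in the neurotrophin list (0.22), the CA3 list (0.12), the choroid plexus list (0.30) and the meninges list (0.88). The fixed neurotrophin, choroid plexus and meninges lists share Igf2 and Igfbp2, so their high values may not be separate. Spatial learning replicate 5 was low in Fos (5.57 against at least 6.47), Mapk8 (8.10) and the Gapdh gap between 3' and 5' signal (0.21), and spatial learning replicate 3 in Hcn2 (4.05) and the list of activity transcription factors (-0.21). Single arrays also stood apart in Gnas (8.67 in control replicate 5), Lpar1 (10.47 in control replicate 1), Nipsnap3b (6.68 in control replicate 3), Ttr (3.66 in spatial learning replicate 4) and the proteasome list (-0.089 in control replicate 5).

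Ttr at 13.41 in control replicate 3 came with other choroid plexus transcripts. The 5 probe sets by which this array stood farthest above the other 11, Ttr, Prlr, F5, Sostdc1 and Enpp2, all belong to the choroid plexus list, 5 of 5 where 32 of 15866 probe sets do, so a fragment of choroid plexus in that dissection is a candidate explanation. Of the 10 by which control replicate 6 and spatial learning replicate 6 both stood farthest above the rest, 5 belong to the meninges list (Col1a2, Col1a1, Ogn, Ptgds and Col3a1), and meningeal tissue may account for these in 1 array of each group. Control replicates 3 and 6 alone do not carry the whole group difference of Ttr. The other 4 controls still lay above all 6 spatial learning arrays (exact permutation p = 0.00476, 5.79 on average against 4.23). The gap was narrow, since these controls ranged from 4.55 to 7.54 and the highest spatial learning array was at 4.43. Whether traces of choroid plexus or the task itself lay behind that remainder cannot be told apart. The other 4 leading transcripts differed by a median of 0.0054 between 5 controls, all but replicate 3, and the spatial learning arrays. Of these, Prlr, F5 and Sostdc1 lay near background outside control replicate 3 (means 2.75, 3.65 and 1.63), and Enpp2 was high on every array (mean 9.35 outside that replicate, 0.16 higher in the 5 controls), which would hide a small share. Ttr against the other choroid plexus list members gave a Spearman rho of 0.53 (permutation p = 0.0789, adjusted over 2 relations 0.0789; Pearson r 0.70, permutation p = 0.0137, adjusted 0.0274). Without the 2 farthest arrays r was -0.08 and rho 0.25, so that the Pearson r rests on these 2. The fixed choroid plexus and meninges lists share Igf2 and Igfbp2, so the choroid plexus score may partly follow meningeal transcripts. Spatial learning replicate 6 was high in both lists (0.30 and 0.88, minus the mean over all arrays) with Ttr at 4.43.

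The control probe sets, which entered no comparison of genes, showed a larger 3' to 5' gap of hexokinase after spatial learning, by 0.17 (log2), in 5 of 6 arrays above the highest control, while that of Gapdh was 0.37 in both groups. Over 951 genes with 2 or more probe sets, the dimmer ones minus the brightest averaged -1.62 ± 0.03 in the control task group and -1.66 ± 0.01 in the spatial learning group (SD, n = 6, exact permutation p = 0.00433). With the hexokinase gap as a covariate this difference of -0.04 (SE 0.01) became -0.02 (SE 0.02), so RNA integrity may account for it. The covariate itself differs between the groups and its slope within them was -0.13 (SE 0.07), so an effect of the task on these probe sets, such as a change in transcript ends, stays open and untested.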

How the results depend on the processing

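Fits without chosen arrays, the hexokinase covariate and the synaptic list without 2 members were added after seeing the data; causes were not tested. With array weights, 1 probe set passed higher (Dgkz) and 2 lower (Cit, Map1b); without control replicates 3 and 6, 0 and 2; without these and spatial learning replicate 6, 2 and 3; leaving out single arrays, 0 to 1 and 0 to 2, above 0 only without control replicate 6. All other settings gave 0. The 611 higher probe sets at unadjusted p under 0.05 became 951 without the filter and 340 with the hexokinase covariate, and the 437 lower ones 265 with that covariate and 244 with 1 probe set per gene, which tests fewer. The deviations gave no general sign that the replicate numbers paired the arrays: same-numbered arrays correlated at -0.17 to 0.08, and 2 of 12 arrays matched their own number best. Control replicate 6 and spatial learning replicate 6 nevertheless were both highest in the meninges list (1.05 and 0.88, minus the mean over all arrays), so a pairing of that number is not excluded. With the replicate block 403 were higher and 366 lower, no probe set passed, and 1 list was higher and 3 lower.

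No list was higher with the CA3 and dentate covariate (0), the estimated correlation (0) or fry (0). Lists called lower, 2 in the report, numbered 6 without the filter, 1 with a common median, 4 with array weights, 1 with the CA3 and dentate covariate, 6 with the hexokinase covariate, 5 without the 3 arrays, 5 with the mean and 4 with the most variable probe set of a gene, and 0 with the estimated correlation and with fry. Without the 3 arrays and with the estimated correlation, 0 were higher and 0 lower (synaptic vesicle -0.097, CA1 0.18, dentate -0.18, activity transcription factors 0.0047, other activity genes -0.0066). Leaving out single arrays gave 1 to 2 higher and 1 to 7 lower, 7 without spatial learning replicate 6. The synaptic vesicle median (-0.11 with the estimated correlation and fry, not called) was -0.064 with the CA3 and dentate and -0.069 with the RNA quality covariate, both called, ranged from -0.11 to -0.070 without single arrays, called in 12 of 12, and was -0.08 without Cplx2 and Slc17a6 (camera adjusted p = 0.000174). The CA1 median, 0.14 and not called with the estimated correlation or fry, was 0.060 with the CA3 and dentate covariate, not called, and 0.089 to 0.18 without single arrays, called in 12. The dentate call was lost, besides the estimated correlation and fry (-0.19), with a filter at 6 (-0.094), a common median (-0.19), covariates for CA3 and dentate (-0.060, built partly from the list itself), choroid plexus (-0.19), RNA quality (-0.14) and hexokinase (-0.20), without the 2 controls (-0.17) and without the 3 arrays (-0.18); without single arrays it ranged from -0.22 to -0.087, called in 8 of 12, and was -0.044 without the filter, still called. The activity transcription factors ranged from -0.047 to 0.017, called only without control replicate 2 (adjusted p = 0.0309), and the other activity genes from -0.033 to -0.0055. Of the lists not called in the report, astrocytes were lower in 14 of 31 other fits (among them no filter, array weights, the choroid plexus and RNA quality covariates, the mean and the most variable probe set), cholesterol synthesis in 11, oligodendrocytes in 9 (no filter, array weights, the choroid plexus covariate), cold and clock in 7, cytoskeleton in 5 (the mean probe set, the hexokinase covariate and 3 single arrays left out), meninges in 2, microglia in 1, and choroid plexus in 1 of 30. Oxidative phosphorylation was higher in 1. The heat shock median turned to -0.045 and was called lower without the 3 arrays. Of 2616 fits of single genes 32 changed sign, 9 passed the threshold and 5 moved by over 1 SD; of 836 fits of other lists 70 changed sign and 52 passed. Dim probe sets near background limit what the arrays show.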

Other observations

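All genes in the next paragraph were named after their values were seen, and the test of dentate tissue alone was added after the report's results but before its own. The counts of splits by their smaller direction and by both directions together were added after the others were seen.

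Some genes had several probe sets that differed alike. In 31 of the 951 genes with 2 or more tested probe sets, 2 or more had an unadjusted p under 0.05 in one direction. As many came in 3 of 100 splits of the arrays, the real one included, and up to 53 in another split. A selection of them follows, mostly neuronal ones. On the lower side, with 17 genes in all, were Rgs4, Adcyap1r1, the receptor of the neuropeptide PACAP (2 of 3 probe sets, -0.55 to -0.38), Synpr, the vesicle protein synaptoporin (-0.63 to -0.45), Marcks, a protein kinase C substrate (3 of 5, -0.35 to -0.16), Hpcal1, a neuronal calcium sensor (-0.43 to -0.25), and Slc17a7 (-0.35 to -0.18). On the higher side, with 14, were Bok and Map4, Tpm1, a tropomyosin (2 of 5, 0.20 to 0.26), Sorl1, a sorting receptor (3 of 5, 0.12 to 0.26), Prkcb, protein kinase C beta (0.10 to 0.12), Camkv (0.11 to 0.18) and Wfs1 (0.29 on both). Among the higher genes outside this selection were Prl8a4 (0.28 to 0.33), Trdn (0.23 to 0.26) and P22k15 (0.19 on both), so the selection does not stand for the whole.

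The lower synaptic vesicle list was set against chance, tissue and RNA integrity. None of the other splits drawn gave this list as small a camera p (1 of 100 with the real one, 2.65e-07 against 9.03e-07 for the next). The list had the smallest camera p of the 32 tested on these arrays, and each split was compared on it alone. Another split gave the CA1 markers a camera p of 4.77e-08, so this count does not exclude chance. The difference of the synaptic vesicle list mean, -0.12, stayed more than 2 SE below 0 with each covariate. It was -0.12 (SE 0.04) with hexokinase, -0.090 (SE 0.02) with CA3 and dentate markers and -0.080 (SE 0.03) with dentate markers alone. The hexokinase gap comes from a single control transcript and itself differs between the groups. The CA3 and dentate scores rest on 11 and 9 genes. Such covariates may correct too little, so neither RNA integrity nor less tissue of those fields is excluded. An effect of the task on presynaptic transcripts in CA1 remains a hypothesis, found and tested on the same arrays. The synaptic vesicle list was not called with an estimated correlation (camera adjusted p = 0.355) or with fry (adjusted p = 0.301). Tissue of other regions and cell types, such as thalamus or subiculum (list of neighbouring regions, camera adjusted p = 0.224), also stays open.

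Few splits gave as many small p values as the real one, while chance was not excluded for the list counts or the synaptic vesicle, CA1 and dentate lists. The 611 probe sets higher at unadjusted p under 0.05 were matched by 2 of 100 splits in their larger direction, the real one included (highest other 615), and both directions together, 1048, by 2 (highest other 1199). These shares are under 5% but not corrected for the several counts tried, and another split gave more. The 437 lower were matched by 5 of 100 in the larger direction of a split (highest other 615) and by 3 in its smaller one (highest other 584), so whether chance is excluded for them depends on the direction counted. The 0 probe sets past the adjusted threshold in each direction are matched by 100 of 100 splits (highest other 17) whatever the data, which shows nothing. The 1 list higher was matched by 94 and the 2 lists lower by 78 (highest other 9), and all 3 together by 71 (highest other 10). A camera p as small as the real one came in 5 of 100 splits for the CA1 markers (0.000688, smallest other 4.77e-08) and in 8 for the dentate markers (0.00437, smallest other 0.000117), so chance was not excluded for either. A split that called 17 probe sets or 9 lists may reflect a structure of the samples other than the task, or correlated probe sets and genes. Neither was tested.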
